A study of Mus musculus with 32 samples.

How the data were processed

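Rearranged heavy chain genes were read from genomic DNA of pro-B cells (B220+ CD43+ IgM- CD25-) of control (WT) and Setd2 knockout (KO) mice 8 weeks old. Per the labels, each PCR joined a primer of 1 VH family (Vh558, Vh7183 or Vhq52) to JH4, a 500 bp product was taken from the gel, and reads of 150 bp were made on a MiSeq. The label text on library making also names poly-A selection and an RNA kit beside genomic DNA; that wording was left as it stands. Setd2 itself is not measured by these amplicons, so the genotype of a mouse rests on its label.

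The 32 samples came from 11 mice (5 WT, 6 KO). Vh558 had 13 samples (6 of 4 WT mice, 7 of 5 KO mice) in 3 sequencing batches, Vh7183 had 10 (5 WT, 5 KO) and Vhq52 had 9 (5 WT, 4 KO), each of these in a single batch. The mouse was the replicate: values of repeat libraries of a mouse were averaged, and their clonotypes were summed for the V gene test. Mouse numbers recur across the amplicons and name the same animal, which was used for a comparison of amplicons within mice.

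Clonotypes are CDR3 sequences with their V, D and J genes. The deposited clone tables follow the layout of MiXCR, which the series title names; its version and settings are not given in the sources used here, nor is a genome build. Values of the clone columns are counts of reads per clonotype as the authors deposited them, with no normalization. The authors' second clone column is a fraction, the reads of a clonotype over all clone reads of its library. Further deposited columns of the series table are other quantities: positions and trimmed lengths in nucleotides within the CDR3, and a text column with aligned reads and their percentage.

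There were 2 sources of clones. A table over the whole series held 930 entries, all productive and of at least 2 reads, with mouse gene names. Clone lists of the single samples (33 lists, from 1 read) held 2111 clonotypes in all frames, of which 1187 were in frame, and their V and D names were those of the human locus: only 45.6% of their V hits and 12.1% of their D hits are names in the mouse gene table, against 100% of the V, D and J hits in the series table. The series table was therefore used for diversity, CDR3 length, segments and V genes, and the single lists for the in-frame share. This choice was made after the tables had been opened and before any test. Of the used series table clonotypes, 908 in number with 124973 reads, 694 (76.4%), holding 99.3% of those reads, were also in the list of their sample. There were 2 libraries of the series table that were not used here: a second run of KO mouse 1534, and an extra library of KO mouse 1500 that matched no sample. The single lists hold both runs of KO mouse 1534, and values from these lists (the in-frame share, out-of-frame joins and the single lists as alternative source) average both. Gene names were looked up in the mouse gene table, and positions along the locus were not printed.

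Richness was the expected number of clonotypes at 1 read depth per amplicon (612 reads for Vh558, 749 for Vh7183, 2012 for Vhq52), the smallest library of at least 500 reads; it was analysed as log2. Diversity was Shannon entropy in bits over clone reads. Other measures were the percentage of reads in the largest clonotype, the mean CDR3 length over clonotypes, the in-frame share, JH and D family shares, junction trimming and inserted bases, and the mean V gene number, which rises with distance from the D genes. Inserted bases were those between V, D and J, or all bases between V and J in clonotypes without a D segment. Values over all amplicons were centred per amplicon and averaged per mouse. A mouse with a single amplicon weighs as much as a mouse with all of them. The amplicons also hold unlike sets of mice, so a difference over all amplicons can exceed that of each amplicon. Differences are KO minus WT with a two-sided exact permutation test over mice and a 95% interval from inverting that test. The smallest p the design allows is 0.00794 in each amplicon and 0.00216 over all amplicons. Benjamini-Hochberg adjustment ran over 23 tests of repertoire measures, 45 of segments and junctions (including the one-sided test of Bray-Curtis distances between V profiles), and 12 of depth.

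V gene usage was tested with edgeR 4.0.16 (quasi-likelihood; limma 3.58.1; R 4.3.3) on clonotypes per V gene and mouse, with the total clonotypes of a mouse as offset. Genes with at least 10 clonotypes were tested, at an adjusted p of 0.05. DESeq2 1.42.0 was the other tool. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest. Named V genes were fixed as those past the threshold, the 8 with the most clonotypes per amplicon, the tested ones nearest to and farthest from D, and IGHV5-2. Also fixed were all 4 JH genes, the DFL16, DSP2, DST4 and DQ52 families, and each clonotype over 25% of the reads of a mouse. Tests, alternatives and this rule were fixed before the data were examined, apart from those called later choices in the closing section.

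The steps were tested on simulated data. The exact test found a shift of 3 standard deviations in 96.5% of simulated sets of 4 WT against 5 KO mice and a shift of 2 standard deviations in 68.75%; without a shift it passed in 5.5%. With the dispersion of these data, edgeR found 35% of genes changed 4-fold, 50% changed 8-fold and 80% changed 16-fold in Vh558. Of genes changed 8-fold it found 92.5% in Vh7183 and 82.5% in Vhq52. Among unchanged genes 0.938%, 2% and 0% passed in Vh558, Vh7183 and Vhq52.

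Intervals for single shares are Wilson 95% intervals, and a count of 0 is given an upper limit of 3 counts. Reads are PCR copies without molecular identifiers, so these cover counting error only. To see whether a mouse keeps its level across amplicons, deviations from the genotype mean were correlated between amplicons for 4 measures, which made 12 relations over 7 to 9 mice. The lowest permutation p was 0.0386, for CDR3 length in Vh558 and Vh7183 (Pearson's r 0.710, adjusted p = 0.240, Spearman's rho 0.476 with permutation p = 0.243). Without the 2 mice farthest from the median that r was -0.182, so the relation rests on them. Alternatives covered read minima, merging of near-identical CDR3 sequences, shared clonotypes, V family filters, weighting, rarefaction, repeat libraries, batches, normalization, filters, tools and leaving out each mouse.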

Results

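Heavy chain variable regions are assembled in pro-B cells by joining a D to a JH gene and then a V to the DJ unit. SETD2 is the methyltransferase that places trimethylation on lysine 36 of histone H3 over transcribed genes. The amplicons ask what the rearranged heavy chain genes of pro-B cells looked like with and without Setd2, in 3 VH families: Vh558 (IGHV1, the large family far from D), Vh7183 (IGHV5, close to D) and Vhq52 (IGHV2). Control (WT) and Setd2 KO mice were compared within each amplicon, with 4 WT and 5 KO mice in Vh558, 5 WT and 5 KO in Vh7183, and 5 WT and 4 KO in Vhq52.

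Libraries held few clonotypes for their depth. Vh558 libraries had 612 to 6927 kept reads and 7 to 188 clonotypes in WT mice, and 1000 to 9276 reads and 5 to 36 clonotypes in KO mice. In Vh7183 the WT libraries had 1033 to 1457 reads and 13 to 35 clonotypes, against 387 to 3045 reads and 9 to 17 clonotypes in KO mice. Vhq52 libraries had 2012 to 7585 reads and 10 to 28 clonotypes in WT mice, and 2246 to 4422 reads and 7 to 14 clonotypes in KO mice. Sequenced reads per library ran from 7789 to 121353. None of the 12 depth comparisons (sequenced reads, aligned share, kept reads) differed by an exact permutation test, with a lowest p of 0.254 (adjusted p = 0.872).

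Libraries of KO mice held fewer productive clonotypes at equal read depth in each of the 3 amplicons, by point estimate. Equal read depth does not equalize template molecules, and cell and DNA input are not given. In Vh558 the geometric mean was 25.6 clonotypes in WT and 8.67 in KO mice, a log2 difference of -1.56 (95% interval -3.79 to 0.56), and of -0.97 without WT mouse 1536. Vh7183 had 19.1 against 12.99 clonotypes (log2 difference -0.55), without KO mouse 1500, whose library of 387 reads was under the minimum. That was -0.35 without WT mouse 1484 and -0.26 without libraries with over 10% of reads in shared sequences. With at least 10 reads per clonotype it was -0.17 (exact p = 0.611). Vhq52 had 16.1 against 10.7 clonotypes (log2 difference -0.60, and -0.38 without KO mouse 1421). Over all amplicons the log2 difference was -1.03 (95% interval -2.02 to -0.02), a KO to WT ratio of 0.489, in 5 WT and 6 KO mice. Exact permutation p-values were 0.198 for Vh558, 0.0952 for Vh7183, 0.230 for Vhq52 and 0.0498 over all amplicons, where the adjusted p was 0.286. That p rests on the set of mice and on the settings. It stayed under 0.05 in 3 of the 11 sets that left out 1 mouse, and in 2 of 7 other settings (highest exact p = 0.0649). Without WT mouse 1536 the value was -0.80 (exact p = 0.114). Within the Vh558 batch of 3 WT and 3 KO mice the log2 difference was -1.13 (exact p = 0.5). Within that of 2 and 2 mice it was -3.45 (exact p = 0.333). Neither batch can reach the threshold, and the remaining batch held a single WT mouse.

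Shannon diversity, which also weighs how evenly reads are spread over clonotypes, was lower in KO mice in the same 3 amplicons by point estimate. Vh558 had 3.89 ± 2.16 bits (SD, n = 4) in WT and 2.002 ± 0.908 bits (SD, n = 5) in KO mice. Vh7183 had 3.23 ± 0.919 bits (SD, n = 5) against 2.24 ± 0.420 bits (SD, n = 5), and Vhq52 had 2.58 ± 0.805 bits (SD, n = 5) against 1.77 ± 0.727 bits (SD, n = 4). The difference over all amplicons was -1.39 bits (95% interval -2.56 to -0.175), with 2 of 6 KO mice below every WT mouse. By exact permutation test p was 0.151 in Vh558, 0.0714 in Vh7183, 0.175 in Vhq52 and 0.0281 over all amplicons. The last had an adjusted p of 0.286, so it did not pass the adjustment over 23 tests. WT mouse 1485 was low in every amplicon, with 1.37, 1.95 and 1.90 bits. Without it the difference had an exact p of 0.0357 in Vh558 (-2.72 bits), 0.00794 in Vh7183 (-1.30 bits) and 0.00476 over all amplicons (-1.79 bits). Without WT mouse 1536 it was -1.20 bits in Vh558. In Vh7183 it was -0.984 bits, and -0.471 bits without libraries with over 10% of reads in shared sequences (exact p = 0.314). In Vhq52, libraries had up to 96.7% of reads in shared sequences, so these mice were not fully independent. That share counts all reads of a shared sequence, also where the other mouse held few. For 13 of 17 pairs of read counts the lower was at or under 5% of the higher. Leaving out libraries with over 10% of reads in shared sequences kept 2 WT and 2 KO mice there, too few for the test to reach 0.05. Without WT mouse 1418, 1484 or 1536 or KO mouse 1421 the value over all amplicons was -1.30, -1.19, -1.13 or -1.33 bits, with exact p-values of 0.0524, 0.0667, 0.0667 and 0.0556. Within Vh558 batches the difference was -1.47 bits (3 against 3 mice, exact p = 0.4) and -3.57 bits (2 against 2 mice, exact p = 0.333). The genotype difference was not shown to differ between amplicons: Vh558 minus Vh7183 was -0.900 bits (exact p = 0.444), Vh558 minus Vhq52 was -1.08 bits (exact p = 0.372) and Vh7183 minus Vhq52 was -0.176 bits (exact p = 0.706). In sets without 1 mouse they ran from -1.42 to -0.194, from -1.74 to -0.384 and from -0.388 to 0.185 bits, the smallest sizes of the former 2 being those without WT mouse 1536 and without WT mouse 1418. With mice as blocks, the paired values were -0.936 bits (exact p = 0.4, 8 mice), -0.895 bits (exact p = 0.514, 7 mice) and -0.283 bits (exact p = 0.579, 9 mice).

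**Figure D1:**
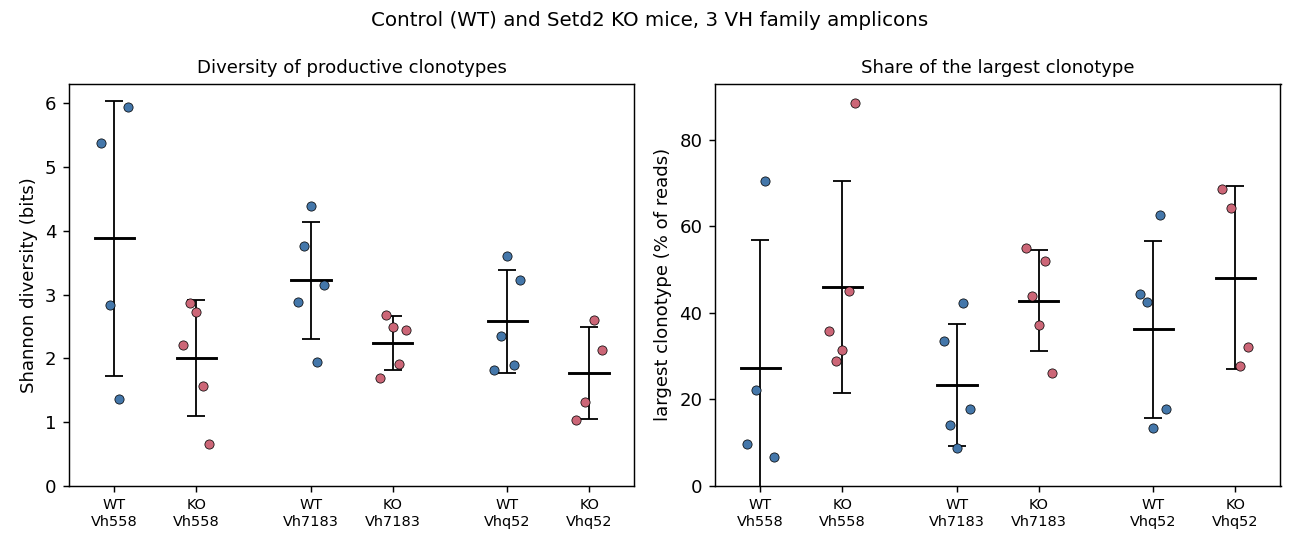
Shannon diversity in bits (left) and percentage of reads in the largest clonotype (right) for each amplicon, with 1 point per mouse, WT in blue and KO in red; thick lines are means and error bars are 1 SD, drawn no lower than 0. Mean diversity was 3.89, 3.23 and 2.58 bits in WT mice and 2.002, 2.24 and 1.77 bits in KO mice of Vh558, Vh7183 and Vhq52, with overlap of the genotypes in each amplicon.

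Single clonotypes took a large part of the productive reads in KO libraries. A clonotype with over 25% of the productive reads of a library was present in 5 of 5 KO and 1 of 4 WT mice in Vh558, in 5 of 5 KO and 2 of 5 WT mice in Vh7183, and in 4 of 4 KO and 3 of 5 WT mice in Vhq52. Productive reads were 24.95% to 99.8% of all clone reads of a library, and over all clone reads these counts were lower, apart from that of WT mice in Vh558. They were then 4 of 5 KO and 1 of 4 WT mice in Vh558, 3 of 5 KO and 0 of 5 WT mice in Vh7183, and 1 of 4 KO and 2 of 5 WT mice in Vhq52, where the direction turned. The Vhq52 clonotypes of KO mice 1464, 1487 and 1500 went from 64.2%, 27.7% and 32.1% of productive reads to 16.0%, 15.3% and 21.1% of clone reads, and those of KO mice 1464 and 1500 in Vh7183 from 37.1% and 26.1% to 12.8% and 12.3%. The Vhq52 clonotype of KO mouse 1464 (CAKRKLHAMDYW) was also that of WT mouse 1418, so the same sequence counts in both genotypes. The largest was an IGHV1-72 to IGHJ4 join of KO mouse 1534 (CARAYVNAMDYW) with 88.5% of 1000 productive reads (Wilson 95% interval 86.4% to 90.3%). KO mouse 1421 had an IGHV2-3 to IGHJ4 join (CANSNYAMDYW) with 68.6% of 4180 reads (67.2% to 70.0%), and an IGHV5-2 to IGHJ4 join (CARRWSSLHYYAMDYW) with 55.1% of 1129 reads (52.2% to 58.0%). In WT mice, mouse 1485 had an IGHV1-72 to IGHJ4 join (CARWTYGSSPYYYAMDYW) with 70.5% of 6488 reads (69.3% to 71.6%). Such a clonotype did not always recur in a repeat library of the same mouse. The repeat Vh558 libraries of KO mouse 1423 had different ones, an IGHV1-22 join with 26.6% and an IGHV1-61 join with 31.0%. Those of KO mouse 1421 had the same one (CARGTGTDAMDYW), with 38.9% and 33.0%. Over all 22 such libraries the V genes included IGHV1-22, IGHV1-55, IGHV1-61, IGHV5-4, IGHV5-12, IGHV5-17, IGHV2-2, IGHV2-9 and IGHV2-9-1, and every one of these clonotypes used IGHJ4. Among all clonotypes IGHJ4 was also the most common JH gene (702 of 908), and the PCR primer lay at JH4.

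The largest clonotype held on average 27.2% ± 29.6 (SD, n = 4) of productive reads in WT and 45.9% ± 24.6 (SD, n = 5) in KO mice of Vh558, where p was 0.349 by exact permutation test. That difference of 18.7 points was 8.10 points without KO mouse 1534, 11.9 points without WT mouse 1536 and 33.2 points without WT mouse 1485. In Vh7183 it held 23.3% ± 14.1 (SD, n = 5) and 42.9% ± 11.7 (SD, n = 5), a difference of 19.5 points (95% interval 1.17 to 37.9) with an exact p of 0.0476 and an adjusted p of 0.286. Vhq52 had 36.2% ± 20.4 (SD, n = 5) against 48.2% ± 21.2 (SD, n = 4), with an exact p of 0.397. That difference of 12.0 points was 5.13, 6.60, 6.25 and 7.36 points without KO mouse 1421 or 1464 or WT mouse 1484 or 1536, and 18.6 and 18.8 points without WT mouse 1485 or KO mouse 1487. Over all amplicons the difference was 21.9 points (95% interval -4.12 to 49.2, exact p = 0.0887, adjusted p = 0.313). This difference exceeded that of each amplicon, and was 14.4 points without KO mouse 1534, which had a library in Vh558 alone. With the single clone lists, which hold all reading frames, it was 11.8 points over all amplicons, 7.79 points in Vh558 and 3.95 points in Vhq52. As percentage of all clone reads it was 11.9, 8.33 and 2.71 points, and 13.6 points in Vh7183 (exact p = 0.111). Within Vh558 batches it was 21.1 points (3 against 3 mice, exact p = 0.5) and 24.2 points (2 against 2 mice, exact p = 0.333). With 1 mouse left out, the Vh7183 difference ran from 15.9 to 24.3 points and had an exact p under 0.05 in 3 of 10 sets (without WT mouse 1418 or 1485 or KO mouse 1500). It had an exact p of 0.0714 with the single clone lists (14.5 points) and 0.114 without libraries of which over 10% of reads were sequences also held by another mouse (15.8 points).

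Heavy chain CDR3 sequences, the part of the antigen binding site made by the V to D to J junctions, were shorter on average in KO mice. Mean length was 45.1 ± 0.910 nt (SD, n = 4) in WT and 41.6 ± 4.28 nt (SD, n = 5) in KO mice of Vh558, 44.1 ± 1.15 nt (SD, n = 5) and 40.7 ± 5.35 nt (SD, n = 5) in Vh7183, and 42.2 ± 3.09 nt (SD, n = 5) and 40.2 ± 3.23 nt (SD, n = 4) in Vhq52. Over all amplicons the difference was -3.53 nt (95% interval -5.91 to -0.735), and 5 of 6 KO mice lay below every WT mouse. The exception, KO mouse 1464, averaged 49.1 nt in Vh558, where the difference without it was -5.40 nt (exact p = 0.0286). The Vh7183 difference of -3.37 nt was -1.62 nt without KO mouse 1487. That of -1.99 nt in Vhq52 was -0.718, -1.001 and -3.03 nt without KO mouse 1421, WT mouse 1536 or KO mouse 1500. Exact permutation p-values were 0.167, 0.198 and 0.381 for Vh558, Vh7183 and Vhq52 and 0.0216 over all amplicons, where the adjusted p was 0.286. Within Vh558 batches the difference was -2.69 nt (3 against 3 mice, exact p = 0.4) and -4.67 nt (2 against 2 mice, exact p = 0.333). With the single clone lists the difference over all amplicons was -1.32 nt in all reading frames (exact p = 0.234) and -0.858 nt in their in-frame clonotypes (exact p = 0.478). Among IGHJ4 joins of the series table it was -1.84 nt (exact p = 0.288). By amplicon, the single lists gave -1.80 nt in Vh558, -1.75 nt in Vh7183 and 0.0182 nt in Vhq52, where the sign turned. Weighted by reads, the Vhq52 difference was -0.702 nt.

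**Figure D2:**
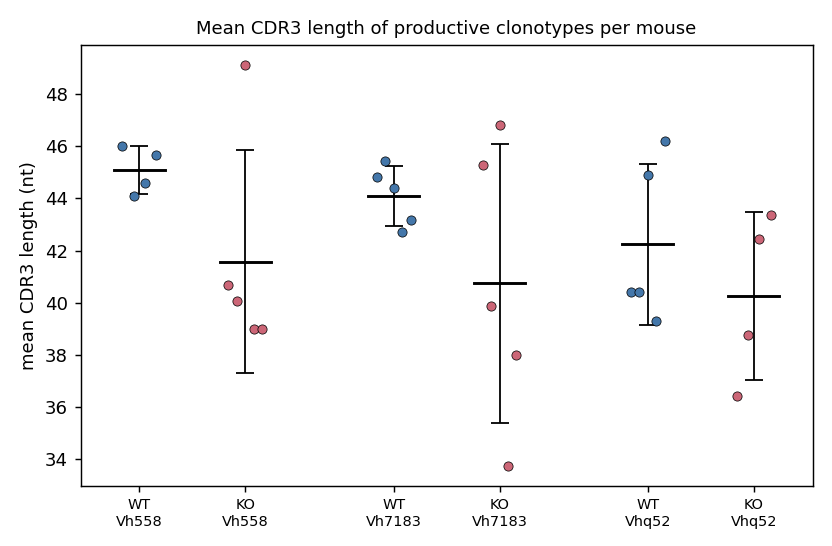
Mean CDR3 length in nt of productive clonotypes per mouse, by amplicon and genotype (WT blue, KO red); thick lines are means and error bars are 1 SD. WT means were 45.1, 44.1 and 42.2 nt and KO means 41.6, 40.7 and 40.2 nt in Vh558, Vh7183 and Vhq52, and the KO mouse at 49.1 nt in Vh558 is mouse 1464.

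Junctions themselves showed no difference that passed a test. Bases inserted between the gene segments averaged 8.04 ± 1.19 nt (SD, n = 4) in WT and 7.04 ± 2.41 nt (SD, n = 5) in KO mice of Vh558, 7.15 ± 0.523 nt and 6.41 ± 2.64 nt (SD, n = 5 each) in Vh7183, and 6.12 ± 1.28 nt (SD, n = 5) and 6.72 ± 2.41 nt (SD, n = 4) in Vhq52. Exact permutation p-values were 0.468, 0.548 and 0.659. The Vh558 difference of -0.998 nt was -0.265, -0.634, -1.77 and -1.53 nt without KO mouse 1421, WT mouse 1432, KO mouse 1464 or WT mouse 1485, and -0.451 nt weighted by reads. Leaving out 1 mouse turned the sign in the other amplicons, with -1.58 to 0.0658 nt in Vh7183 and -0.308 to 1.61 nt in Vhq52. A D segment was found in 88.9%, 87.1% and 89.6% of clonotypes of WT mice and in 85.9%, 78.5% and 84.5% of those of KO mice (exact p = 0.437, 0.214 and 0.595). Where none was found, all bases between V and J counted as inserted, which includes any D remnant that was not recognized. Trimming of V ends averaged 0.617, 0.491 and 1.39 nt in WT mice and 0.468, 0.417 and 1.89 nt in KO mice, and that of J starts 3.53, 3.50 and 3.90 nt against 5.04, 3.45 and 3.28 nt (lowest exact p = 0.206, J starts in Vh558).

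The share of in-frame joins in the clone lists showed no difference that passed a test. In Vh558 73.7% ± 13.4 (SD, n = 4) of WT and 60.4% ± 17.9 (SD, n = 5) of KO clonotypes were in frame without a stop, by exact test p = 0.262. That difference of -13.3 points was -6.49 points without KO mouse 1500. Vh7183 had 47.7% ± 16.4 and 50.1% ± 6.62 (SD, n = 5 each, exact p = 0.778), a difference of 2.43 points that was 15.1 points without libraries with over 10% of reads in shared sequences (exact p = 0.0571). Vhq52 had 34.4% ± 6.93 (SD, n = 5) and 36.6% ± 10.9 (SD, n = 4, exact p = 0.730). That difference of 2.18 points ran from -10.2 to 2.99 points over 6 other settings, 3 of which reversed its sign. The difference over all amplicons was -0.711 points, and its interval of -12.4 to 10.5 points leaves differences of that size open (exact p = 0.896). Within Vh558 batches it was -14.3 points (exact p = 0.4) and -11.5 points (exact p = 1). These lists include 2 runs of KO mouse 1534 in Vh558, of which the other measures use 1. Without the second list the difference over all amplicons was 0.122 points (exact p = 0.978). The lists carry human gene names, and their in-frame calls rest on the CDR3 sequences alone. Many of their clonotypes had a single read, such as 76 of 147 in Vhq52 of WT mouse 1484 and 14 of 32 of KO mouse 1421. With at least 10 reads per clonotype the difference over all amplicons was -6.40 points (exact p = 0.381).

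By group mean, IGHJ4 was the most used JH gene in WT mice of every amplicon, and its share was lower in KO mice by point estimate. It was 78.5% ± 20.4 (SD, n = 4) of clonotypes in WT and 66.8% ± 17.4 (SD, n = 5) in KO mice of Vh558, 62.8% ± 10.8 (SD, n = 5) and 40.1% ± 28.1 (SD, n = 5) in Vh7183, and 48.8% ± 14.0 (SD, n = 5) and 36.7% ± 7.22 (SD, n = 4) in Vhq52. Exact permutation p-values were 0.389, 0.119 and 0.159. The Vh558 difference of -11.7 points was -4.95, -4.997 and -6.89 points without WT mouse 1536, KO mouse 1534 or WT mouse 1418, and -18.8 points without WT mouse 1485. IGHJ3 had 8.16% ± 4.68 (SD, n = 5) in WT and 28.6% ± 22.4 (SD, n = 5) in KO mice of Vh7183, with 4 of 5 KO mice above every WT mouse (exact p = 0.0952). IGHJ2 had 19.0% ± 15.4 (SD, n = 5) and 32.5% ± 5.44 (SD, n = 4) in Vhq52 (exact p = 0.159), and IGHJ1 stayed at or under 8.54% in every group mean. None of these passed the adjustment over 45 tests, where the lowest adjusted p was 0.861. A primer at JH4 gives longer products for joins to the JH genes upstream of it, and a 500 bp band was cut, so these shares are those of the amplified band. For IGHJ4 in Vh7183, counting reads gave -10.2 points (exact p = 0.0476), clonotypes of at least 10 reads gave -44.0 points (exact p = 0.0476), and leaving out KO mouse 1500, at 88.9%, gave -34.9 points (exact p = 0.00794). Counting reads left -0.776 points in Vh558 (from -11.7) and -0.386 points in Vhq52 (from -12.1), and clonotypes of at least 10 reads gave -6.94 and 2.70 points there. For IGHJ3 in Vh7183 these settings moved the difference of 20.4 points between 9.19 and 32.2 points (exact p = 0.0476 in both, unadjusted). With 1 mouse left out it ran from 12.8 to 27.5 points, with an exact p under 0.05 in 1 of 10 sets. Shared sequences were not left out for JH shares. WT mice 1432 and 1484 shared 9 of them in Vh7183, so the mice there were not fully independent.

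Among D families, DFL16 (IGHD1) was the one with the lowest p. In Vh7183 it was 43.0% ± 12.1 (SD, n = 5) of D-bearing clonotypes in WT and 15% ± 17.2 (SD, n = 5) in KO mice, with 4 of 5 KO mice below every WT mouse (exact p = 0.0317, adjusted p = 0.861). The other amplicons had the opposite sign for DFL16: 30.3% ± 27.6 (SD, n = 4) and 37.5% ± 35.4 (SD, n = 5) in Vh558 (exact p = 0.738), and 27.8% ± 21.4 (SD, n = 5) and 32.9% ± 22.4 (SD, n = 4) in Vhq52 (exact p = 0.690). That sign rests on single mice: Vh558 had -8.38 points without KO mouse 1534 and -1.29 points without WT mouse 1432, and Vhq52 had -0.557 points without KO mouse 1464 and -6.71 points with at least 10 reads per clonotype. DSP2 (IGHD2) was the most used family in WT mice of Vh558 and Vhq52, with 48.0% and 57.0% of clonotypes against 39.0% and 48.7% in KO mice (exact p = 0.556 in both), and in Vh7183 it had 39.1% and 54.3% (exact p = 0.190). DQ52 (IGHD4), the D gene next to JH, had 8.77%, 7.08% and 6.05% in WT and 13.5%, 23.8% and 12.8% in KO mice (lowest exact p = 0.317). DST4 (IGHD3) was 5.67% ± 3.53 (SD, n = 5) in WT mice and 0% in 4 KO mice of Vhq52 (exact p = 0.0476, adjusted p = 0.861; under 0.05 in 1 of 9 sets that left out 1 mouse). Those KO mice had 37 D-bearing clonotypes, so 0 allows a share of up to 8.11%, which is above the WT mean. The DST4 difference of -5.67 points shrank to between -3.18 and -2.62 points when weighted by reads or with at least 10 reads per clonotype. Its exact p was then 0.325 to 0.444. DFL16 in Vh7183 had an exact p of 0.0794 when reads were counted (-30.7 points) and stayed under 0.05 in 5 of the 10 sets that left out 1 mouse. Without WT mouse 1418 or 1485 or KO mouse 1423, 1487 or 1500 it was -24.6, -24.8, -27.5, -24.2 and -24.2 points. Shared sequences were not left out for D families either, and WT mice 1432 and 1484 shared 9 of them in Vh7183.

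**Figure D3:**
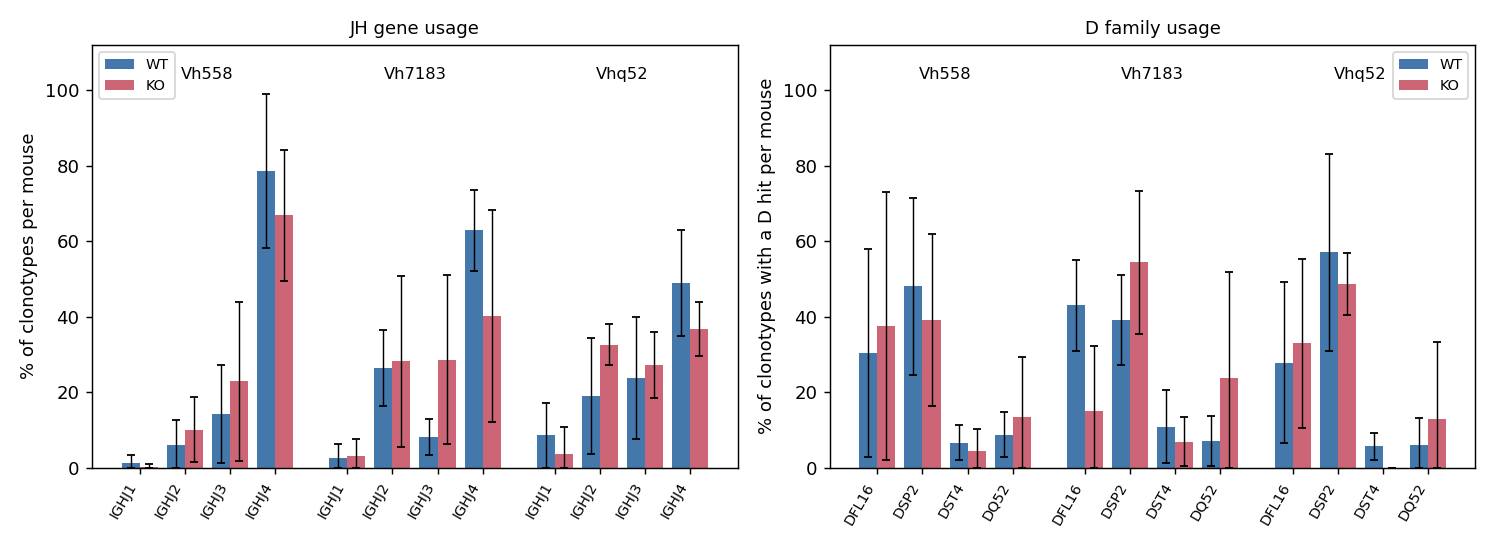
JH gene usage as percentage of clonotypes (left) and D family usage as percentage of clonotypes with a D segment (right), by amplicon; bars are means over mice (WT blue, KO red; n = 4 and 5 in Vh558, 5 and 5 in Vh7183, 5 and 4 in Vhq52) and error bars are 1 SD, drawn no lower than 0. IGHJ4 means were 78.5% and 66.8% in Vh558, and DFL16 means were 43.0% and 15% in Vh7183.

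In the Vh558 amplicon 24 V genes of the IGHV1 family were found in 602 clonotypes (476 WT, 126 KO), and the 8 most used held 64.8% of them. A clonotype in both repeat libraries of a mouse counts 2 times here. Counted once, 0 of 16 genes passed. WT mice 1418 and 1536, which had repeat libraries, held 205 and 241 of the 476 WT clonotypes, so pooled WT shares are mostly theirs. IGHV1-26 was the most used gene of WT mice, with 16.5% ± 3.81 (SD, n = 4) against 6.77% ± 8.35 (SD, n = 5) in KO mice (log2 change fitted by edgeR -1.50). IGHV1-55 had 9.92% ± 9.20 in WT and 21.0% ± 24.3 in KO mice, and IGHV1-72 had 16.1% ± 18.1 and 12.6% ± 10.5 (SD, n = 4 and 5), with a fitted log2 change of the other sign (0.15). IGHV1-53 had 8.72% and 4.72%, IGHV1-74 had 6.24% and 2.37%, IGHV1-18, the tested gene nearest to D, had 4.75% and 5.80%, and IGHV1-19 had 3.56% and 7.28%. For these 2 genes the fitted log2 changes had the other sign than the means per mouse, -0.97 and -0.089, as had the pooled shares (7.14% WT and 2.38% KO, and 6.72% WT and 3.97% KO). IGHV1-81, the tested gene farthest from D, had 1.67% ± 2.82 (SD, n = 4) and 7.22% ± 12.9 (SD, n = 5). Of its 22 KO clonotypes, 20 came from the repeat libraries of mouse 1423 and need not all be distinct. Of 16 genes tested with edgeR, 0 passed and 2 had an unadjusted p under 0.05, IGHV1-81 (edgeR adjusted p = 0.355) and IGHV1-75. DESeq2 also passed 0, with 1 under 0.05 unadjusted. IGHV1-75, named after its values were seen, had 27 clonotypes in WT mice 1418 and 1536 and 0 of 126 in KO mice (edgeR adjusted p = 0.202). The other WT mice had none either. By counting alone, 0 of 126 allows a KO share of up to 2.38%, against a pooled WT share of 5.67%. Both shares pool clonotypes over mice and leave out the spread between mice. With clonotypes of at least 10 reads, IGHV1-81 passed (log2 change 3.14, edgeR adjusted p = 0.0317; over the alternatives its adjusted p ran from 0.0317 to 0.994).

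Vh7183 clonotypes used 12 V genes, and the 8 most used, all of IGHV5, held 89.3% of the 168 clonotypes. IGHV5-17, the tested gene farthest from D, had 14.4% ± 3.67 (SD, n = 5) in WT and 29.1% ± 28.2 (SD, n = 5) in KO mice, with a fitted log2 change of 1.12. IGHV5-4 had 17.7% ± 6.47 and 21.8% ± 21.5, IGHV5-6 had 15.9% ± 6.68 and 11.3% ± 10.8, and IGHV5-12 had 11.3% ± 9.36 and 13.2% ± 12.8 (SD, n = 5 each). IGHV5-2 (VH81X), the most D-proximal functional V gene and the one preferred in early rearrangement, had 11.3% ± 6.81 (SD, n = 5) in WT and 10.8% ± 7.68 (SD, n = 5) in KO mice, with a fitted log2 change of the other sign (0.16, edgeR adjusted p = 0.951). That fitted sign turned in 2 of 7 other settings and in 4 of 10 sets that left out 1 mouse. Of the genes with too few clonotypes to test, IGHV5-16 had 6.47% and 1.82% and IGHV5-9 had 4.29% and 3.15%. IGHV5-9-1 had 9 clonotypes in 3 WT mice and 0 of 64 in KO mice. By counting alone 0 allows up to 4.69%, against a pooled WT share of 8.65%, without the spread between mice. Of 5 genes tested with edgeR, 0 passed and 0 had an unadjusted p under 0.05, and DESeq2 gave 0 and 0. Counting reads instead of clonotypes, IGHV5-9-1 could be tested and passed (edgeR adjusted p = 0.0363); its fitted change is set by the count of 0.

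In Vhq52 all 138 clonotypes used 7 V genes of IGHV2. IGHV2-2, the tested gene nearest to D, had the highest share in both genotypes, with 47.5% ± 13.4 (SD, n = 5) in WT and 54.9% ± 15.5 (SD, n = 4) in KO mice. IGHV2-3 had 20.2% ± 13.5 (SD, n = 5) and 9.42% ± 13.5 (SD, n = 4). Its KO to WT ratio fitted by edgeR, which is not the ratio of these means, was 0.326 (edgeR adjusted p = 0.185). IGHV2-9-1, the tested gene farthest from D, had 13.3% ± 2.89 (SD, n = 5) and 12.1% ± 10.5 (SD, n = 4), and IGHV2-5 had 10.4% ± 7.33 (SD, n = 5) and 2.27% ± 4.55 (SD, n = 4). IGHV2-6 had 4.18% and 10.3%, IGHV2-9 had 3.56% and 9.20%, and IGHV2-6-8 had 0.8% and 1.79%; these were too few to test. Of 4 genes tested with edgeR, 0 passed and 1 had an unadjusted p under 0.05; DESeq2 gave 0 and 0.

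**Figure D4:**
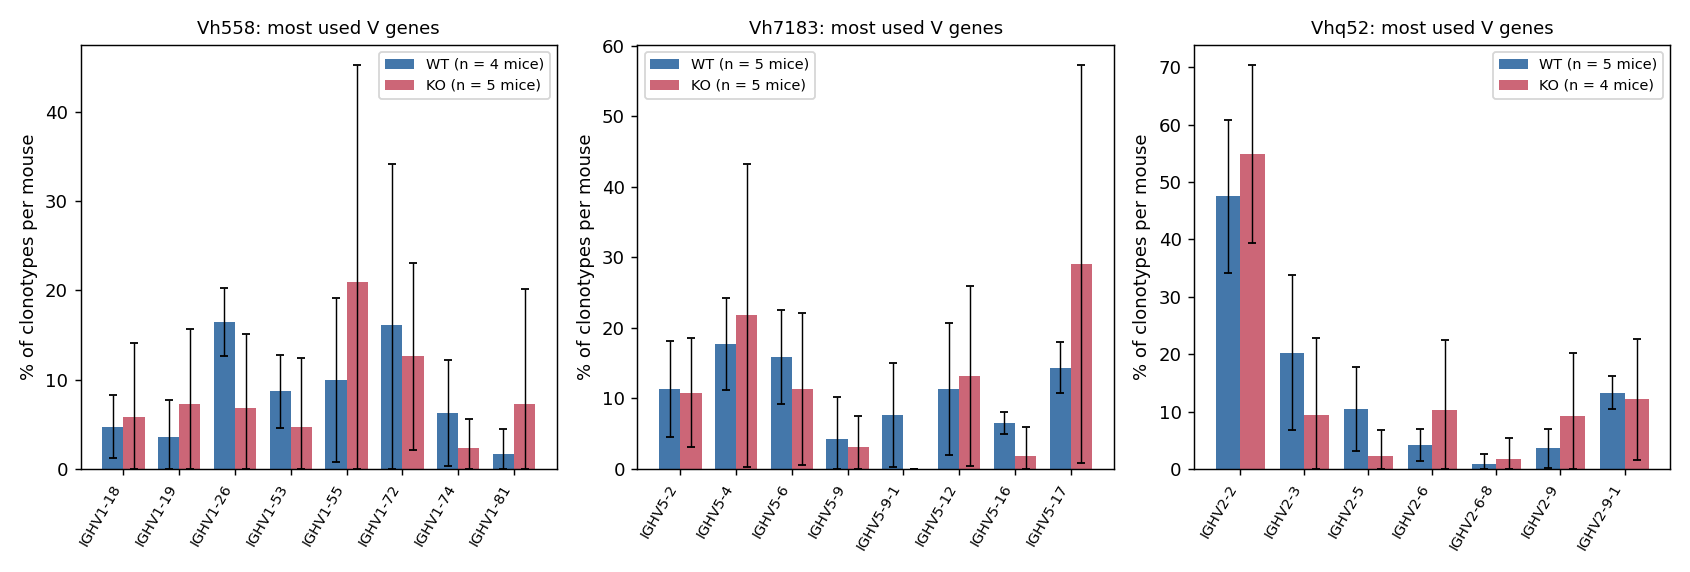
Percentage of clonotypes per mouse for the most used V genes of each amplicon, ordered by gene number; bars are means (WT blue, KO red), error bars are 1 SD drawn no lower than 0, and the legends give the number of mice. IGHV1-26 had 16.5% in WT and 6.77% in KO mice, IGHV5-2 had 11.3% and 10.8%, and IGHV2-2 had 47.5% and 54.9%.

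Usage of V genes near to and far from D showed no difference that passed a test. The mean V gene number was 52.1 ± 5.93 (SD, n = 4) in WT and 52.4 ± 11.1 (SD, n = 5) in KO mice of Vh558 (exact p = 0.976), 8.83 ± 0.859 and 9.83 ± 3.03 (SD, n = 5 each) in Vh7183 (exact p = 0.484). The Vh7183 difference was 0.246, 0.290, 1.84 and 1.71 without KO mouse 1464, 1423, 1421 or 1500, and 0.314 weighted by reads. In Vhq52 the values were 3.89 ± 0.381 (SD, n = 5) and 4.14 ± 1.38 (SD, n = 4, exact p = 0.690). Whole V profiles were not shown to be closer within than between genotypes: the mean distance between genotypes minus that within them was -0.0273 in Vh558, 0.0473 in Vh7183 and 0.0297 in Vhq52, with one-sided exact permutation p-values of 0.722, 0.0952 and 0.206. The Vh7183 value was 0.121 without KO mouse 1421 (exact p = 0.00794) and 0.0559 without KO mouse 1464 (exact p = 0.0476), and the Vhq52 value was 0.0795 without KO mouse 1500 (exact p = 0.0179). Other settings went the other way: Vh7183 had 0.00147 without WT mouse 1484, 0.0130 weighted by reads and -0.0210 with at least 10 reads per clonotype, and Vhq52 had 0.00315 without WT mouse 1484, 0.00966 with at least 10 reads and -0.0536 weighted by reads. Shared sequences were not left out for these distances. WT mice 1432 and 1484 shared 9 in Vh7183, and WT mice 1418 and 1536 shared 7 in Vhq52. Such sharing lowers distances within WT mice, so the mice were not fully independent in these tests. The edgeR test found 35% of simulated 4-fold changes in Vh558, so changes of that size in single V genes were mostly not detectable there.

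Off-target products could be looked for only among clonotypes, and 11.1% to 57.8% of the reads of a library were aligned. Of the clonotypes in the single lists, 1 in Vh558, 0 in Vh7183 and 2 in Vhq52 had a V or J hit outside the heavy chain locus, each with a single read. In the series table, clonotypes of other VH families were found in Vh7183 alone, where they were 17 clonotypes (10.1%) with 2.27% of reads, 14 of IGHV6 and 3 of IGHV7.

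Identical CDR3 sequences occurred in different mice of the same amplicon and batch. Of 105 pairs of libraries of different mice in 1 batch and amplicon, 13 pairs shared sequences (23 distinct ones, 32 when summed over pairs), against 0 of 50 pairs in different batches and 0 of 306 pairs of different amplicons. All shared sequences were in Vh7183 (2 of 45 pairs) and Vhq52 (11 of 36 pairs); Vh558 had 0 in 24 pairs of a batch. WT mice 1432 and 1484 shared 9 sequences in Vh7183, and in Vhq52 sequences also held by another mouse made up 96.7% of the reads of WT mouse 1418 and 95.9% of those of KO mouse 1464. An IGHV2-9 to IGHJ4 join (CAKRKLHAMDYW) was the largest clonotype in both of these libraries, with 44.5% and 64.2% of reads. Percentages of shared reads count all reads of a shared sequence, also where the other mouse held few. Repeat libraries of a mouse shared 20 sequences in WT mouse 1418 (126 and 79 clonotypes), 7 in WT mouse 1536 (53 and 188), 11 in KO mouse 1423 (31 and 36) and 1 in KO mouse 1421 (7 and 10). The sequences found in both repeats held from 9.69% (WT mouse 1536) to 42.6% (KO mouse 1423) of the reads of a library.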

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

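The tests below of the spread of shared sequences over pairs of mice, of sharing between batches, of read ratios, of richness at equal read number, of template numbers in repeat libraries, of IGHJ1 to IGHJ3 joins and of other splits of the mice were chosen only after the results they concern had been seen.

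In 121 groups of at least 4 mice (1 measure, amplicon and genotype each), 10 held a mouse far from the others of its genotype. For independent groups of normally spread values chance would mark about 1 in 20, which is 6.05 of 121. The groups here are linked, and in some all other mice were at 0%, so that number is only a rough guide. KO mouse 1464 had a mean CDR3 length of 49.1 nt in Vh558, the other 4 KO mice 39 to 40.7 nt. KO mouse 1534 stood apart in Vh558 with a largest clonotype of 88.5% of productive reads (others 28.8% to 45.0%), a DFL16 share of 100% (others 16.1% to 30%) and an IGHJ3 share of 60% (others 10% to 20%). Its library held 5 clonotypes, so a single one is 20% of them. This mouse had a library in Vh558 alone, so its value over all amplicons is the same observation: its largest clonotype lay 50.9 points above the amplicon mean (other KO mice -3.001 to 15.8 points). In Vh558, IGHJ1 was highest in KO mouse 1423 (1.39%, others 0%) and in WT mouse 1432 (4.35%, others up to 0.633%). In Vhq52 it was highest in KO mouse 1421 (14.3%, others 0%). In Vh7183, WT mouse 1485 had no IGHJ3 clonotype (0%, others 8.57% to 11.1%), and KO mouse 1500 had an IGHJ4 share of 88.9% (others 18.2% to 35.3%).

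Different mice held 23 identical CDR3 sequences, 10 in Vh7183 and 13 in Vhq52, each with 1 V gene in all its mice; 7 were shared across genotypes. Independent identical rearrangements are argued against as the whole cause, because the sequences gathered in single pairs: WT mice 1432 and 1484 shared 9 in Vh7183 and WT mice 1418 and 1536 shared 7 in Vhq52, while 4000 random draws that kept the number of mice per sequence gave a pair at most 5 and 7 (permutation p = 0.000250, the smallest they can give, and 0.0010), and draws of single pairs, run earlier, at most 5 and 9. Inserted bases alone leave this open, with a difference of medians of 0 between shared and other sequences (bootstrap -3 to 2). Reads assigned to the wrong index would give a small ratio of the lower to the higher read count. The median ratio was 4.11% over 27 pairs, which leaves this open as a whole. In Vh7183 it was 45.1% (bootstrap 32.9% to 79.9%). This argues against wrong indexing for the 9 of 10 sequences above 5%, all of WT mice 1432 and 1484. The remaining sequence, of KO mice 1500 and 1423, had 2.06%. In Vhq52 the median was 1.37% (bootstrap 0.651% to 4.11%), where wrong indexing is a candidate explanation for 13 of 17 pairs and not for the 4 above 5%. Carry-over within a batch cannot be told apart from other mixing: 0 sequences were shared between batches or amplicons, but Vh7183 and Vhq52 had 1 batch each and Vh558 shared none within batches either.

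Lower diversity in KO libraries could stem from fewer reads, fewer template molecules or a narrower repertoire. Fewer reads are argued against for richness: the difference over all amplicons was -1.10 (log2) with all reads and -1.03 at equal read number of the same libraries, and the part removed was -0.070 (SE 0.097 over mice). Fewer reads are argued against for Shannon diversity too: the difference over all amplicons was -1.39 bits both before and after thinning to equal read number. Thinning took a mean of only 0.0216 bits per library from that measure. Fewer templates cannot be told apart from a narrower repertoire, because cell and DNA input are not given. Repeat libraries of 2 KO mice gave pool estimates of 43 and 97.7 clonotypes, and those of 2 WT mice 483 and 1275, which either would give. The estimate of 43 rests on 1 shared sequence. The WT mice with repeats, 1418 and 1536, had the highest Vh558 diversity of all mice, 5.39 and 5.95 bits. WT mice 1432 and 1485 had no repeat, and their 2.84 and 1.37 bits lay within the KO range of 0.659 to 2.86 bits. These estimates thus do not stand for all WT mice.

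Shorter CDR3 sequences in KO libraries may come with fewer IGHJ4 joins or with shorter junctions made by recombination itself, before any selection. Neither can be told apart from selection here. Among IGHJ4 joins the difference was -1.84 nt (exact p = 0.288) against -3.53 nt over all joins, too imprecise to separate part of the difference from all of it. Among IGHJ1 to IGHJ3 joins it was -3.02 nt (exact p = 0.0498). Out-of-frame joins, which encode no chain to select on, gave -1.74 nt (SE 1.17, exact p = 0.177), and in-frame joins of the same lists gave -0.858 nt (exact p = 0.478), both too imprecise to decide. No read minimum was set for these joins, so sequencing errors among single-read entries were not separated from real joins.

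Other splits of the mice decide nothing for V gene usage. By edgeR the genotypes had 0 genes past the threshold in Vh558, Vh7183 and Vhq52 (2, 0 and 1 at an unadjusted p under 0.05; DESeq2 0, 0 and 0 past it), so 100 of 100 splits gave as many in each amplicon by construction. The highest of the other splits gave 2, 1 and 1.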

How the results depend on the processing

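The single clone lists as source, leaving out libraries with over 10% of reads in sequences another mouse held, the kept percentage of reads, the rank of V genes, reads of the same V genes, counting each clonotype of a mouse once, the largest clonotype as percentage of all clone reads, the in-frame share without the second list of KO mouse 1534 and IGHJ4 joins alone were tests chosen after seeing the data. Other alternatives were set beforehand. Counts below are of pairs of a result and an alternative; a threshold is an exact p of 0.05 for measures and an adjusted p for V genes. Of the pairs for results that answer a comparison, 188 kept direction and side of the threshold under other settings, 11 reversed, 6 passed newly, 12 no longer passed and 2 counts moved. With 1 mouse left out these numbers were 339, 22, 9, 24 and 0. Of those that kept both, 26 values under other settings were over 1.5 times smaller and 16 over 1.5 times larger, and 57 and 50 with 1 mouse left out. For single segments and V genes, 181 kept both under other settings, 25 reversed, 3 passed newly and 3 no longer passed, and 379, 50, 1 and 14 with 1 mouse left out. Where a value below changed side or sign, the cause was not tested.

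Shannon diversity over all amplicons kept an exact p under 0.05 in 8 of 8 other settings (-1.50 to -1.28 bits), and in 7 of 11 sets with 1 mouse left out (-1.79 to -1.11 bits). CDR3 length over all amplicons kept it in 11 of 11 such sets, but not with the single lists (-1.32 nt), without libraries with shared reads (-3.94 nt) or in IGHJ4 joins alone (-1.84 nt). Richness over all amplicons lost it with at least 10 reads per clonotype (log2 -1.02, exact p = 0.0628), without clonotypes another mouse held with more reads (-0.99), with the primer's VH family only (-1.02), without libraries with shared reads (-1.15) and without rarefaction (-1.09). With 1 mouse left out it ran from -1.35 to -0.80 and lost it without WT mouse 1418, 1432, 1484 or 1536 or KO mouse 1421, 1487, 1500 or 1534. Shannon diversity over all amplicons lost it without WT mouse 1418, 1484 or 1536 or KO mouse 1421.

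In single amplicons, richness in Vh7183 (-0.55) passed without rarefaction (-0.66), but was -0.17 with at least 10 reads (exact p = 0.611) and -0.26 without libraries with shared reads (exact p = 0.286). Leaving out 1 mouse it ran from -0.71 (without WT mouse 1485, exact p = 0.0286) to -0.35. Shannon diversity in Vh7183 passed with near-identical sequences merged (-1.03 bits), with the single lists (-1.16 bits) and as inverse Simpson index (-1.16), but was -0.471 bits without libraries with shared reads (exact p = 0.314, from -0.984). Leaving out 1 mouse gave -1.30 to -0.695 bits there and -2.72 to -1.20 bits in Vh558, passing without WT mouse 1485 in both. In Vhq52 the single lists gave -0.508 bits (exact p = 0.429, from -0.808). The largest clonotype in Vh7183 no longer passed with the single lists (14.5 points), without libraries with shared reads (15.8 points) or as percentage of all clone reads (13.6 points). It ran from 15.9 to 24.3 points and lost it without KO mouse 1421, 1423, 1464 or 1487 or WT mouse 1432, 1484 or 1536. Over all amplicons (21.9 points) it was 11.8 points with the single lists and 11.9 points over all clone reads. It ran there from 14.4 to 29.9 points with 1 mouse left out and passed without WT mouse 1485 (exact p = 0.0143). CDR3 length in Vh558 ran from -5.40 nt (without KO mouse 1464) to -2.87 nt, and in Vhq52 the sign flipped with the single lists (0.0182 nt).

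The in-frame share flipped sign in Vhq52 with at least 10 reads (-10.2 points), as kept percentage (-6.24) and weighted by reads (-2.95), and over all amplicons without libraries with shared reads (0.267 points) and without the second list of KO mouse 1534 (0.122 points). With 1 mouse left out it ran from -2.34 to 8.07 in Vh7183, -1.54 to 6.17 in Vhq52 and -2.81 to 1.80 over all amplicons. The Shannon difference of Vh7183 minus that of Vhq52 ran from -0.388 to 0.185 bits in such sets.

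With at least 10 reads per clonotype, values in points flipped for IGHJ1 in Vh7183 (-2.86), IGHJ3 in Vhq52 (-11.7), IGHJ4 in Vhq52 (2.70), DFL16 in Vhq52 (-6.71), DQ52 in Vh558 (-2.94) and other D genes in Vh558 (1.18). V end trimming in Vh7183 (0.106 nt) and V profile distance in Vh7183 (-0.0210) flipped too, and IGHJ4 in Vh7183 passed (-44.0 points). Weighted by reads, IGHJ4 in Vh7183 passed (-10.2 points) and DFL16 in Vh7183 no longer did (-30.7 points). That weighting flipped IGHJ1 in Vh7183 (-0.110 points), V end trimming in Vh7183 (0.144 nt) and Vhq52 (-0.0525 nt) and V profile distance in Vhq52 (-0.0536). V position in Vh558 flipped by rank (-0.0364).

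Leaving out 1 mouse gave these ranges in points. IGHJ1 had -1.38 to 0.0668 in Vh558 and -0.983 to 1.76 in Vh7183, IGHJ2 -5.73 to 7.38 in Vh7183, and IGHJ3 -0.688 to 13.4 in Vh558 and -2.37 to 7.63 in Vhq52. IGHJ4 in Vh7183 had -34.9 (passing without KO mouse 1500) to -17.2. DFL16 had -8.38 to 19.3 in Vh558, -34.6 to -24.2 in Vh7183 (lost without WT mouse 1418 or 1485 or KO mouse 1423, 1487 or 1500) and -0.557 to 16.1 in Vhq52. DSP2 had -19.5 to 0.715 in Vh558, DQ52 -0.679 to 8.07 in Vh558 and -3.27 to 11.02 in Vhq52, and other D genes -2.88 to 0.599 in Vh558 and -0.152 to 4.02 in Vhq52. The D segment share in Vhq52 had -10.2 to 2.61. In nt, V end trimming had -0.220 to 0.0303 and J start trimming -0.821 to 0.454 in Vh7183, and inserted bases -1.58 to 0.0658 in Vh7183 and -0.308 to 1.61 in Vhq52. V position had -2.67 to 4.74 in Vh558 and -0.250 to 0.860 in Vhq52. V profile distance had -0.0669 to 0.0154 in Vh558, 0.00147 to 0.121 in Vh7183 (passing without KO mouse 1421 or 1464) and 0.00315 to 0.0795 in Vhq52 (passing without KO mouse 1500).

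The number of V genes past the threshold moved from 0 to 1 in Vh558 with at least 10 reads per clonotype (IGHV1-81) and from 0 to 1 in Vh7183 with reads per V gene (IGHV5-9-1, too rare to test as clonotypes). Log2 changes of V genes flipped with reads as counts for IGHV1-19 (2.26), IGHV5-4 (-0.52) and IGHV5-6 (0.12), the same to 2 decimals over the V genes tested as clonotypes. They flipped with TMM for IGHV1-72 (-0.24), IGHV5-4 (-0.38), IGHV5-12 (-0.38), IGHV5-2 (-0.25) and IGHV2-2 (-0.071), and with DESeq2 for IGHV5-4 (-0.63), IGHV5-12 (-0.65) and IGHV5-2 (-0.51). The deepest library of each mouse flipped IGHV1-19 (0.32) and IGHV1-74 (0.24), and at least 10 reads flipped IGHV5-4 (-0.46). With 1 mouse left out the ranges that crossed 0 were -0.55 to 1.52 for IGHV1-55, -0.25 to 0.76 for IGHV1-72, -0.70 to 0.64 for IGHV1-19, -1.17 to 0.10 for IGHV1-53, -0.42 to 0.50 for IGHV5-4, -0.50 to 0.60 for IGHV5-12, -0.24 to 0.39 for IGHV5-2 and -0.54 to 0.19 for IGHV2-9-1.

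The V family filter was not run for the in-frame share, whose source has human V names, and keeping in-frame clonotypes alone moved nothing, since the series table holds productive ones. Batches of Vh558 analysed alone had too few mice to reach the threshold. With the mice, clonotypes and dispersion of these data, edgeR found 35% of simulated 4-fold changes in Vh558. Depth kept KO mouse 1500, with 387 reads, out of richness in Vh7183. Settings that left out shared sequences covered richness, diversity, the largest clonotype, the in-frame share and CDR3 length. They were not run for segments, junctions, V genes or V profile distance.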

Other observations

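The tests over all amplicons in this part were chosen only after the data had been seen. IGHJ4 joins had a mean CDR3 length of 45.3 ± 8.27 nt (SD over 702 clonotypes), against 42.9 ± 5.17 nt for 17 IGHJ1 joins, 39.9 ± 6.60 nt for 101 IGHJ3 joins and 39.3 ± 7.37 nt for 88 IGHJ2 joins. These spreads are over clonotypes pooled from all mice, not over mice. The difference in IGHJ4 share over all amplicons was -19.2 points (5 WT and 6 KO mice, exact permutation p = 0.0325, unadjusted), with 3 of 6 KO mice below every WT mouse. Weighted by reads it was -5.23 points (exact p = 0.0866). With 1 mouse left out it ran from -23.6 to -15.1 points, with an exact p under 0.05 in 5 of 11 sets.

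The difference in the share of clonotypes with a D segment was -6.70 points over all amplicons (exact permutation p = 0.0909), with 4 of 6 KO mice below every WT mouse. For inserted bases it was -0.623 nt (exact p = 0.407), for V end trimming 0.0326 nt (exact p = 0.803) and for J start trimming 0.679 nt (exact p = 0.483). Clonotypes found in both sources had a median of 2.5 times as many reads in the series table as in the single lists.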
